A study of Saccharomyces cerevisiae with 6 samples.

How the data were processed

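The series holds 6 single-colour Affymetrix arrays of total RNA from Saccharomyces cerevisiae grown at 30 °C, 2 each of WT, an FHL1 deletion and a double deletion of FHL1 and IFH1, which the labels number as first and second experiment. The values deposited by the authors are log2 expression summaries, 1 per probe set and array, for 9335 probe sets; the log2 scale was read from their range, and the summarization and normalization methods are not given in the sources used here. Strain backgrounds and growth media are not given in them either.

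Probe sets were named from the platform annotation supplied with the values: 6504 named 1 gene, 328 named several genes and 2503 named none, of which 60 are array controls. All 6504 matched a gene of the reference annotation and gave 5656 genes, of which 315 had several probe sets; for these the probe set with the highest mean was used, and in 4 of them other probe sets were called in the opposite direction in the FHL1 deletion. Probe sets of several genes or none were left out of the gene tests and are counted apart. Each array's median over the named genes was subtracted, values under the 10th percentile (5.63) were raised to it, and the 25% of genes with the lowest mean were left out, which left 4242 genes tested and 1414 not tested. The files name no genome build, so no coordinates are given, and the annotation served for names and gene order only.

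Groups were compared with limma 3.58.1 in R 4.3.3: lmFit with 1 mean per group, then eBayes with a trend of spread on signal. All 6 arrays shared 1 estimate of the spread, with 3 residual degrees of freedom, because 2 against 2 arrays leave few. The p-values were adjusted by Benjamini and Hochberg within each comparison, with a threshold of 0.05, and SE is the standard error of the model. Gene lists were tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over 31 lists in 3 comparisons (93 tests); 42 passed with the preset correlation and 0 with the estimated one, for which 2 had an unadjusted p under 0.05. The lists covered cytosolic ribosomal proteins (137 genes, and the subunits apart), ribosome assembly, RNA polymerases I and III, translation factors, mitochondrial ribosomal proteins, general stress, chaperones, glycolysis, respiration, amino acid synthesis, sulfur, proteasome, hexose transport, galactose, phosphate, ergosterol, iron, cell wall, histones, G1/S, daughter cells, mating type and haploid genes, pheromone, meiosis, strain markers and RNA export. In the lists 2 symbols matched no gene of the annotation or the arrays, and other members had no probe set that names them alone, among them 57 of the 137 ribosomal protein genes. Lists, the tests of genes and lists and the rule for named genes were fixed before the data were examined; the lists matched for brightness and the other tests of explanations were chosen afterwards.

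The genes named are FHL1 and IFH1, per comparison the 10 largest rises and 10 largest falls among genes past the threshold whose arrays did not overlap between the groups (where none passed, the 5 with the smallest p), and up to 3 members with the smallest p from each list that passed or held a called member. Any other gene named, such as neighbours of the deleted genes, members named as exceptions in a list, mating type markers and genes of small counts, was chosen after its values were seen. 

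The link between the comparisons through the shared WT arrays was measured with 100 simulated data sets (for the overlap, chosen after the data were seen, with lists as long as the called ones, ranked by difference over spread), and the ribosomal protein list was set beside 10000 random lists matched for brightness in 40 bins. The model was tested on simulated data in which genes varied independently. It found 10.4% of changes of 0.5, 83.6% of changes of 1 and 98.5% of changes of 2 on the log2 scale, with 4 false calls among 132. On such data camera with the preset correlation gave p under 0.05 for 2 of 100 unshifted lists. That count says nothing of lists whose genes vary together, as on these arrays. The estimated correlation was 0.16 for the cytosolic ribosomal protein list and 0.54 for the general stress list. Camera with an estimated correlation was not tried on simulated data, so its power with these few arrays is unknown. Alternatives were the deposited scaling, quantile normalization, a median without the ribosomal protein genes, floors at the 1st and 25th percentiles, no filter or the lowest 50% left out, the mean of a gene's probe sets, only probe sets with the plain suffix, the experiment number as a block, only the arrays compared, no trend, other WT arrays for each mutant and each array left out in turn. Array set as a block, the 4 arrays with MATalpha markers alone, the estimated correlation with array set as a block, and the ribosomal protein list with probe sets of several genes were added after seeing the data. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.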

Results

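Total RNA from Saccharomyces cerevisiae grown at 30 °C was measured on 6 Affymetrix yeast arrays: 2 of wild type (WT), 2 of a strain deleted for FHL1 and 2 of a strain deleted for both FHL1 and IFH1. FHL1 encodes a forkhead-type protein that binds ribosomal protein gene promoters, and IFH1 encodes the coactivator that works with it there. The comparisons ask which transcripts differ when FHL1 is missing, which differ when both are missing, and what the loss of IFH1 adds to the loss of FHL1. Deposited log2 values had array medians from 7.69 to 7.77, and the 10th percentile of an array lay between 4.35 and 4.78. All fold changes are log2, rest on n = 2 arrays per group unless arrays were left out, and are relative to each array's median. The number of arrays limits the precision, and no label says that the replicates came from separate cultures, so each p-value measures only the spread between these arrays.

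The arrays also fell into sets that the labels do not name. Exactly equal values linked WT of the first experiment with the FHL1 deletion of the second (502 probe sets) and the double deletion of the first (573), and linked these mutant arrays with each other (859). These are called array set A, and the other arrays, which shared 1 equal value at most, array set B. Deviations from the group means correlated across genes at 0.38 between WT and the FHL1 deletion when arrays were matched by set. With 2 arrays per group, matching by experiment number only turns the sign of that value (-0.38), so it is no separate evidence. Between WT and the double deletion both matchings gave 0.42, and between the mutants matching by set gave 0.63. Medians within sets A and B are therefore also given for the lists that passed against WT, except the separate subunit lists, and for some others. Bacterial control probe sets (9), which carry no yeast gene, differed from WT by -0.79 in the FHL1 deletion and by -0.78 in the double deletion, relative to the array median. The 3' minus 5' signal of ACT1, a measure of RNA integrity, was 0.96 and 0.93 on the WT arrays, 1.08 and 1.15 on the FHL1 deletion arrays and 1.07 and 1.02 on the double deletion arrays. That of SRB4 differed more, at 2.25 and 1.52 in WT, 3.09 and 2.39 in the FHL1 deletion and 2.70 and 1.89 in the double deletion (set A first). That of SPT15 was 0.98 and 1.12, 1.11 and 1.22, and 1.23 and 1.14 in the same order. The median of 10 rRNA control probe sets was 9.84 on the WT array of the second experiment, apart from 6.04 on the other WT array and 5.38 to 6.77 on the mutant arrays. Chromosome medians of the mutant arrays stayed between -0.19 and 0.13 of WT.

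The deleted genes came first. IFH1 (YLR223C) had a scaled log2 signal of 8.51 ± 0.18 (SD, n = 2) in WT and 8.91 ± 0.01 (SD, n = 2) in the FHL1 deletion, and it lay at the floor of 5.63 on both double deletion arrays. In the double deletion it was therefore at least 7.35-fold lower than in WT (adjusted p = 0.000434) and at least 9.75-fold lower than in the FHL1 deletion (adjusted p = 0.000339). Between the FHL1 deletion and WT it differed by 0.41 (SE 0.15, adjusted p = 0.0995, and adjusted p = 0.03 with array set as a block). FHL1 (YPR104C) lay under the floor on every array, so no fold is given. Its deposited values were 4.91 and 5.02 in WT, 3.18 and 2.67 in the FHL1 deletion, and 2.66 and 2.89 in the double deletion. HIS3, a histidine synthesis gene widely used as a selection marker, rose by 3.09 (SE 0.15, adjusted p = 0.00049) in the FHL1 deletion and by 3.06 (SE 0.15, adjusted p = 0.000434) in the double deletion.

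The arrays differed in mating type markers. MFA1, which encodes a-factor, had scaled values of 12.87 and 12.83 on the FHL1 deletion array of the first experiment and the double deletion array of the second, and 7.26 to 7.86 on the other 4 arrays. MF(ALPHA)1, which encodes alpha-factor, had 6.89 and 6.96 on those 2 arrays and 12.09 to 13.00 on the others. Both arrays with MATa markers were in set B, whereas both WT arrays carried MATalpha markers. No tested member of the MATa list (3 genes) or of the MATalpha list (5 genes) passed in any comparison, and each mutant group held 1 array of either kind. The MATalpha list gave adjusted p = 0.112 in the FHL1 deletion and 0.119 in the double deletion, and 0.0379 and 0.0426 with array set as a block, where an estimated correlation gave adjusted p = 0.845 for both. The MATa list gave 0.437 and 0.384.

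**Figure D1:**
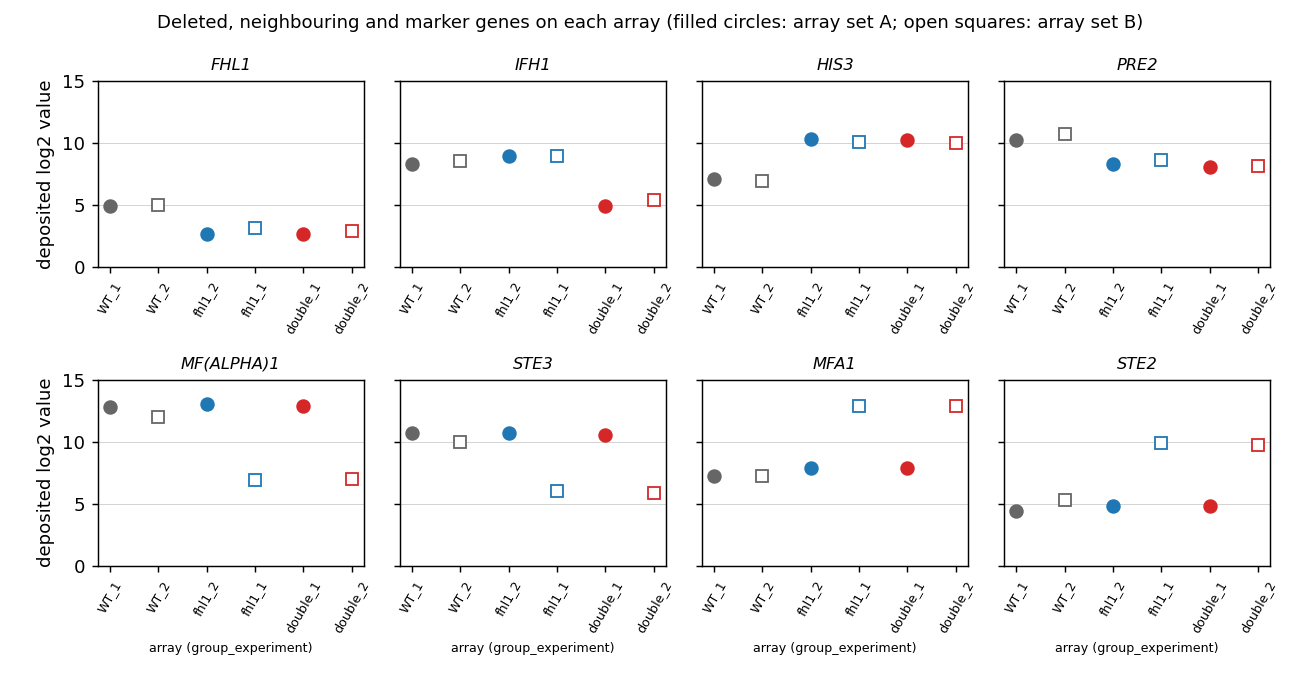
Deposited log2 value of 8 genes on each of the 6 arrays, with filled circles for array set A, open squares for set B, grey for WT, blue for the FHL1 deletion and red for the double deletion. HIS3 lay near 10 on all mutant arrays, IFH1 was lowest on the double deletion arrays, and MFA1 and STE2 were high only on 1 array of each mutant group, where MF(ALPHA)1 and STE3 were low.

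In the FHL1 deletion, falls were called among ribosomal protein genes, and rises in 16 of 36 general stress and 19 of 48 respiration genes. Of 80 cytosolic ribosomal protein genes tested, 26 fell, none rose and 54 did not pass, with a median of -0.33. RPS7B at -1.76 (SE 0.20, adjusted p = 0.00311), RPS22B at -1.42 (SE 0.17, adjusted p = 0.0032) and RPS0A at -1.37 (SE 0.11, adjusted p = 0.0021), which encode proteins of the small subunit, and RPL31B at -1.48 (SE 0.13, adjusted p = 0.00227), of the large subunit, were among the falls. DDR2, a multistress response gene, rose by 3.57 (SE 0.22, adjusted p = 0.000862) and HSP12, a membrane-protecting heat shock protein gene, by 3.04 (SE 0.36, adjusted p = 0.00328). ARG1, an arginine synthesis gene, fell by 3.23 (SE 0.31, adjusted p = 0.00253), and PHO5, a secreted acid phosphatase gene, fell by 2.95 (SE 0.44, adjusted p = 0.00588).

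The ribosomal protein genes shifted by different amounts, with 71 of the 80 tested below 0 and 9 above. The middle of the list ran from -0.61 at the lower quartile to -0.10 at the upper. The large-subunit genes (47 tested) gave 13 falls (18 adjusted over the list alone) and a median of -0.36, with RPL6B at -1.16 and RPL16A at -0.89, and the small-subunit genes (33 tested) gave 13 falls (13 adjusted over the list alone) and a median of -0.33. RPL3 at -0.03 and RPL10 at 0.10, named after their values were seen, lay near 0. The whole list had medians of -0.34 in set A and -0.30 in set B, and 31 falls adjusted over the list alone. Its set test gave adjusted p = 1.89e-10 with a preset correlation and adjusted p = 0.551 with an estimated correlation. The lowest adjusted p with an estimated correlation over all 93 set tests was 0.551. Many lists share that value through the adjustment, so it does not rank them. Before adjustment, camera with an estimated correlation gave this list p = 0.0876 here and p = 0.0503 in the double deletion. The median was -0.22 after quantile normalization.

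Genes of other parts of the translation machinery moved in both directions. Mitochondrial ribosomal protein genes (64 tested) gave 8 falls, including MRP4 at -0.94, MRPL24 at -0.87 and MRPS35 at -0.67, and 1 rise, RSM18 at 0.50. Their median was -0.31 (set A -0.31, set B -0.22) with adjusted p = 0.000106, and adjusted p = 0.646 with an estimated correlation. There were 0 rises and 4 falls adjusted over the list alone. Ribosome assembly genes (126 tested) gave 14 rises and 2 falls around a median of 0.09 and did not pass as a list (adjusted p = 0.181). There were 2 rises and 1 fall adjusted over the list alone. UTP22, which forms a complex with IFH1 besides its role in small-subunit assembly, fell by 0.93 (SE 0.14, adjusted p = 0.00692), whereas BUD21 rose by 0.89 and FCF1 by 0.68. Among genes of the RNA polymerase I machinery (13 tested), RPA12 and RRN3 rose and RRN5 fell, in the RNA polymerase III list (21 tested) RPC34 rose, and among translation factors (30 tested) TEF4 fell by 0.60. None of these lists passed. Adjusted over the list alone, 2 rises and 1 fall passed for polymerase I, none for polymerase III and 1 fall for the translation factors.

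Stress and respiration genes formed the largest groups of rises among the fixed lists. Of 36 general stress genes, 16 rose and 1, GRE2, fell by 0.93; CTT1, the cytosolic catalase gene, rose by 1.89 (SE 0.18) and SPI1, a cell wall protein gene, by 1.49 (SE 0.14). The list median was 0.51 with adjusted p = 3.01e-06, and adjusted p = 0.685 with an estimated correlation. There were 18 rises and 2 falls adjusted over the list alone. Its median was 0.20 in set A and 0.85 in set B, the set in which the mutant arrays carried MATa markers. The gap cannot be assigned to mating type, since the WT arrays, both with MATalpha markers, differed between the sets too. For HSP12 they had 10.69 (set A) and 9.38 (set B), against 13.00 and 13.15 in the FHL1 deletion. For DDR2 they had 10.16 and 9.47, against 13.35 and 13.43. Of 48 tricarboxylic acid cycle and respiration genes, 19 rose and none fell, including the lactate dehydrogenase gene CYB2 at 1.39, the ATP synthase subunit gene ATP20 at 0.99 and the cytochrome oxidase subunit gene COX12 at 0.74. The list median was 0.39 (set A 0.21, set B 0.57) with adjusted p = 0.000927, and adjusted p = 0.766 with an estimated correlation. There were 21 rises adjusted over the list alone. Cell wall genes (29 tested) gave 7 rises, with PIR3 at 2.59, the cell integrity kinase gene SLT2 at 0.94 and NCW2 at 0.69, and 8 adjusted over the list alone. Their median was 0.27 (set A 0.08, set B 0.40) with adjusted p = 0.0218, adjusted p = 0.818 with an estimated correlation and adjusted p = 0.0529 with array set as a block. Over the 4 arrays with MATalpha markers, with 1 array of each mutant, it was 0.12 (adjusted p = 0.324), and the list did not pass without the FHL1 deletion array (0.12, adjusted p = 0.335) or the WT array of the first experiment (adjusted p = 0.0744). The proteasome list (33 tested) gave 4 rises, including RPN8 at 0.61 and RPN13 at 0.51, and 1 fall, the catalytic subunit gene PRE2 at -2.12 (SE 0.20). Its median was 0.24 (set A 0.22, set B 0.29) with adjusted p = 0.0261, and adjusted p = 0.766 with an estimated correlation. Adjusted over the list alone 0 rises and 1 fall passed. Over the MATalpha arrays the list gave adjusted p = 0.181, without the WT array of the second experiment a median of 0.15 (adjusted p = 0.211), and without the FHL1 deletion array of the second experiment adjusted p = 0.139.

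Of 53 amino acid synthesis genes, 19 fell and 1, the transcription factor gene GCN4, rose by 0.43; besides ARG1, the histidine gene HIS4 at -1.47 and the aromatic pathway gene ARO2 at -1.004 were among the falls. The median was -0.38 (set A -0.36, set B -0.40) with adjusted p = 6e-07. There were 2 rises and 26 falls adjusted over the list alone. Sulfur and methionine genes (21 tested) gave 7 falls, among them the sulfite reductase gene MET5 at -1.01, the sulfate permease gene SUL2 at -0.93 and the ATP sulfurylase gene MET3 at -0.92, and 1 rise, MMP1 at 0.84. Their median was -0.46 (set A -0.41, set B -0.48) with adjusted p = 0.0008. There were 1 rise and 11 falls adjusted over the list alone. Phosphate genes (13 tested) gave 8 falls and 1 rise, PHM8 at 1.04; the vacuolar phosphatase gene PHO8 fell by 1.21 and the polyphosphate synthesis gene VTC2 fell by 1.12. Their median of -1.11 (set A -1.09, set B -1.03) was the lowest among lists that passed, with adjusted p = 0.00016 and adjusted p = 0.59 with an estimated correlation. There were 1 rise and 10 falls adjusted over the list alone. Of 17 glycolysis genes 4 fell, with the hexokinase gene HXK2 at -1.09, PFK1 at -0.55 and PGK1 at -0.43, and 6 adjusted over the list alone. Their median was -0.33 (set A -0.36, set B -0.17) with adjusted p = 0.00114, and -0.20 after quantile normalization. Of 26 chaperone genes 5 fell, including HSP82 at -0.95, HSP60 at -0.63 and SSA1 at -0.59, and 6 adjusted over the list alone. Their median was -0.21 (set A -0.21, set B -0.24) with adjusted p = 0.0118, -0.10 in the deposited scaling, with adjusted p = 0.0667 without the WT array of the first experiment and adjusted p = 0.0956 over the MATalpha arrays. The amino acid, sulfur, glycolysis and chaperone lists each had adjusted p = 0.551 with an estimated correlation. Of 8 hexose transport genes 4 fell, HXT4 at -2.20, HXT1 at -1.14, HXT2 at -0.92 and HXT3 at -0.67, with a list adjusted p of 0.0447, adjusted p = 0.0576 with array set as a block and adjusted p = 0.551 with an estimated correlation. Adjusted over the list alone 4 falls passed, and the list median of -0.36 (set A -0.41, set B -0.39) became 0.03 when all probe sets of a gene were averaged and 0.04 without the WT array of the first experiment. The list also lost its call after quantile normalization (adjusted p = 0.0663), with no filter (-0.06, adjusted p = 0.183) and with more dim genes left out (adjusted p = 0.187).

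Further lists held called members but did not pass. Iron genes (17 tested, median 0.15, set A 0.46, set B -0.04) gave 3 rises, HMX1 at 1.13, CTH1 at 0.91 and ISU1 at 0.85. The G1/S list (24 tested) gave 1 rise, the cyclin gene PCL1 at 1.83, and 3 falls, including the DNA ligase gene CDC9 at -0.87 and the cohesin gene SMC3 at -0.61. Daughter-cell genes (11 tested) gave 3 falls, SUN4 at -0.96, DSE4 at -0.73 (-0.45, adjusted p = 0.183, without the FHL1 deletion array of the second experiment) and EGT2 at -0.62, and 1 rise, CTS1 at 0.38. In the haploid list (11 tested) STE18, a mating G protein subunit gene, rose by 1.68 and HO, the mating type switching endonuclease gene, fell by 1.74. The pheromone list (7 tested) had 1 rise, PRM5 at 1.06, the galactose list (2 tested) 1 rise, GCY1 at 2.11, and the RNA export list (12 tested) 3 rises, GSP2 at 1.11 (0.60, adjusted p = 0.109, without the WT array of the second experiment), MTR2 at 0.72 and YRA1 at 0.55. In the ergosterol list (23 tested) ERG8 rose by 0.57 and ERG12 fell by 1.07. The strain marker list (10 tested) gave 3 rises, with ADE2 at 0.75, and 3 falls, with MET17 at -0.56. Adjusted over the list alone, 3 rises passed for iron genes, 1 rise and 2 falls for G1/S, 1 rise and 3 falls for daughter-cell genes, 1 rise and 1 fall for the haploid list, 1 rise each for the pheromone and galactose lists, 3 rises and 2 falls for RNA export, 1 fall for ergosterol, and 4 rises and 4 falls for strain markers. Histone genes (4 tested) and the meiosis list (1 tested) had no called member in any comparison.

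Among all 4242 tested genes, 546 rose and 357 fell in the FHL1 deletion, 131 and 100 of them by more than 2-fold. The largest rise was YDR034C-A at 4.94 (SE 0.69, adjusted p = 0.00539), followed within the top 10 by DDR2, HIS3, HSP12, the serine deaminase gene CHA1 at 2.83, PIR3, the cytochrome oxidase subunit gene COX26 at 2.52, RTC3 at 2.30, CPP3 at 2.23 and MNC1 at 2.12. The largest falls after ARG1 and PHO5 were the rRNA precursor RDN37-1 at -2.59 (SE 0.37), HXT4, the mitochondrially encoded ATP synthase gene OLI1 at -2.18, the small nucleolar RNA SNR44 at -2.14, HMS2 at -2.13, PRE2 and the phosphate regulator gene SPL2 at -1.97. The polyphosphatase gene PPN2 fell too, without a rank, since the FHL1 deletion array of the second experiment lay at the floor; without it the value was -1.38 (adjusted p = 0.0137). With the floor at the 25th percentile, and without the WT array of the first experiment, another probe set of RDN37-1 became the brightest, which gave -0.31 (adjusted p = 0.913) and adjusted p = 0.313. The probe set given here differed by -2.40 without that array. In the deposited scaling, which raised the median of all genes by 0.11, 74.2% of 1036 called genes were higher, against 60.5% in the main scaling. The count was 1767 with array set as a block, with all 903 genes among them, and 505 with the experiment number as a block. Without the WT array of the first or the second experiment it was 319 or 243, and without the FHL1 deletion array of the second experiment 472. Of 81 named genes called here, the call ended for 34 or 37 without the WT array of the first or the second experiment, and for 18 or 19 without the FHL1 deletion array of the first or the second.

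In the double deletion, of 80 cytosolic ribosomal protein genes, 39 fell, none rose and 41 did not pass, with a median of -0.47 (set A -0.57, set B -0.41). The falls included RPS7B at -1.93 (SE 0.20, adjusted p = 0.00256), RPS0A at -1.58 (SE 0.11, adjusted p = 0.000909), RPL33B at -1.57 (SE 0.16, adjusted p = 0.00256) and RPL6B at -1.497 (SE 0.16, adjusted p = 0.00279), with RPS22B at -1.43 and RPL31B at -1.26. The large-subunit genes gave 22 falls around a median of -0.49 (32 adjusted over the list alone) and the small-subunit genes 17 falls around -0.42 (17 adjusted over the list alone), while 18 genes, among them RPL3 at 0.01 and RPL10 at 0.12, lay within 0.2 of 0. The set test gave adjusted p = 4.33e-16, and adjusted p = 0.551 with an estimated correlation. There were 51 falls adjusted over the list alone. Probe sets shared by several ribosomal protein genes (58 tested) had medians of -0.46 here and -0.30 in the FHL1 deletion, with 21 and 14 lower.

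The mitochondrial ribosomal protein genes gave 25 falls and no rise, with MRP4 at -1.12, MRPL1 at -1.01 and MRPL24 at -0.95. Their median was -0.50 (set A -0.53, set B -0.46) with adjusted p = 1.33e-10, and adjusted p = 0.551 with an estimated correlation. There were 37 falls adjusted over the list alone. Ribosome assembly genes passed as a list with a median of 0.19 (set A 0.22, set B 0.13, adjusted p = 0.00279, and adjusted p = 0.685 with an estimated correlation), and with 0.10 (adjusted p = 0.126) without the WT array of the first experiment they did not. They gave 7 rises, including CGR1 at 0.76 and RRP3 at 0.75, and 1 fall, UTP22 at -0.89, and none of these passed when adjusted over the list alone. RRN3 at 0.65, RRN7 at 0.67 and RPC34 at 0.82 rose, and RRN5 at -0.64, TEF4 at -0.57 and STM1 at -0.51 fell, in polymerase and translation factor lists that did not pass. Adjusted over the list alone, 2 rises and 1 fall passed for polymerase I, 1 rise for polymerase III and none for the translation factors.

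General stress genes gave 15 rises and 2 falls, with DDR2 at 3.39, HSP12 at 2.86 and SPI1 at 1.49 among the rises and GRE2 and HXK1 as the falls. Their median was 0.42 (set A 0.23, set B 0.67) with adjusted p = 0.000168, and adjusted p = 0.759 with an estimated correlation. It was 0.71 without the WT array of the first experiment. There were 18 rises and 2 falls adjusted over the list alone. Respiration genes gave 8 rises, with CYB2 at 1.30, the cytochrome c gene CYC1 at 0.80 and COX12 at 0.60, and 1 fall, LSC2 at -0.66, also when adjusted over the list alone. Their median was 0.30 (set A 0.08, set B 0.49) with adjusted p = 0.00609, and adjusted p = 0.784 with an estimated correlation, and the list did not pass without the WT array of the second experiment (0.17, adjusted p = 0.167). Cell wall genes gave 11 rises and no fall, with PIR3 at 3.06, the protease gene YPS3 at 1.37 and the glucan synthase gene GSC2 at 1.15. Their median was 0.34 (set A 0.26, set B 0.48) with adjusted p = 1.97e-05, and adjusted p = 0.685 with an estimated correlation. There were 13 rises adjusted over the list alone. Iron genes passed with a median of 0.40 (set A 0.56, set B 0.07, adjusted p = 0.00833, and adjusted p = 0.685 with an estimated correlation) and 3 rises, also over the list alone: the heme oxygenase gene HMX1 at 1.35, the iron-sulfur scaffold gene ISU1 at 1.02 and the reductase gene FRE2 at 0.79. The iron median was 0.14 (adjusted p = 0.409) without the WT array of the first experiment and 0.64 without that of the second.

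Amino acid synthesis genes gave 18 falls, with ARG1 at -3.22, ARO2 at -1.03 and ILV6 at -0.88, and 1 rise, GCN4 at 0.43. Their median was -0.41 (set A -0.49, set B -0.39, adjusted p = 8.18e-07). There were 2 rises and 23 falls adjusted over the list alone. Sulfur and methionine genes gave 12 falls, with MET5 at -1.39, MET17 at -1.23 and MET3 at -1.07, around a median of -0.65 (set A -0.85, set B -0.53, adjusted p = 3.61e-06), and 15 falls adjusted over the list alone. Phosphate genes gave 6 falls, with GIT1 at -1.64, PHO8 at -1.30 and VTC2 at -1.05, and 1 rise, PHM8 at 1.07. Their median was -0.72 (set A -1.06, set B -0.38, adjusted p = 0.00121, and adjusted p = 0.646 with an estimated correlation), with 1 rise and 8 falls adjusted over the list alone. Glycolysis genes gave 3 falls (HXK2 at -1.01, PFK1 at -0.49 and PGK1 at -0.44) around -0.31 (set A -0.33, set B -0.17, adjusted p = 0.00191), the same number adjusted over the list alone. After quantile normalization the list gave -0.16 with adjusted p = 0.06. Chaperone genes gave 5 falls, with HSP82 at -0.83, HSP60 at -0.63 and SSA1 at -0.56, around -0.23 (set A -0.22, set B -0.27, adjusted p = 0.00432), and 6 adjusted over the list alone. Hexose transport genes gave 3 falls, also adjusted over the list alone, with HXT4 at -1.85, HXT1 at -0.62 and HXT3 at -0.50, around -0.33 (set A -0.46, set B -0.25, adjusted p = 0.0402, and adjusted p = 0.0551 with array set as a block). It was -0.085 (adjusted p = 0.0943) without the WT array of the first experiment, -0.43 (adjusted p = 0.0536) without that of the second and -0.19 (adjusted p = 0.0973) without the double deletion array of the first. The amino acid, sulfur, glycolysis, chaperone and hexose lists each had adjusted p = 0.551 with an estimated correlation.

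The proteasome list did not pass (median 0.14, adjusted p = 0.213), and its only called member was PRE2 at -2.44 (SE 0.20, adjusted p = 0.00144). Further called members of lists that did not pass included PCL1 at 1.89, GCY1 at 1.80, STE18 at 1.36, PRM5 at 1.24, PRM4 at 0.68, ADE2 at 0.99, MTR2 at 0.66 and ERG8 at 0.63 as rises, and HO at -1.51 (-0.88, adjusted p = 0.119, without the double deletion array of the second experiment), SUN4 at -0.85, CDC9 at -0.78, EGT2 at -0.72, ERG12 at -0.63 and SMC3 at -0.51 as falls. Adjusted over the list alone, 1 fall passed for the proteasome, 1 rise and 2 falls for G1/S, 2 falls for daughter-cell genes, 2 rises and 1 fall for the haploid list, 2 rises for the pheromone list, 1 rise each for galactose and RNA export, none for ergosterol, and 4 rises and 5 falls for strain markers.

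Over all tested genes 415 rose and 359 fell in the double deletion, 113 and 93 of them by more than 2-fold. The top 10 rises were YDR034C-A at 3.43 (SE 0.69, adjusted p = 0.0196, and 2.14 without the double deletion array of the first experiment), DDR2, HIS3, PIR3, HSP12, CHA1 at 2.67, NCA3 at 2.56, MNC1 at 2.53, the vitamin B6 synthesis gene SNZ1 at 2.24 (1.45, adjusted p = 0.0987, without that array) and CPP3 at 2.22. The largest falls were ARG1, PRE2, SNR44 at -2.37, PHO5 at -2.26 (SE 0.44, and -1.47 without that array), HMS2 at -2.02, RPS7B, HXT4, RDN37-1 at -1.85 and the small nucleolar RNA SNR39 at -1.80, beside IFH1, whose value at the floor gives no rank. With the floor at the 25th percentile another probe set of RDN37-1 was the brightest, and its value turned to 2.02 (adjusted p = 0.418). Without the WT array of the first experiment that other probe set gave -0.26 (adjusted p = 0.944), while the probe set given here differed by -1.65. In the deposited scaling 65.9% of 790 called genes were higher, against 53.6% in the main scaling. The count was 1577 with array set as a block, with all 774 genes among them, 315 with the experiment number as a block and 461 with no filter on dim genes. Without the WT array of the first or the second experiment it was 207 or 133, and without the double deletion array of the first or the second experiment 330 or 288. Of 76 named genes called here, the call ended for 32 or 40 without the WT array of the first or the second experiment, and for 24 or 22 without the double deletion array of the first or the second.

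**Figure D2:**
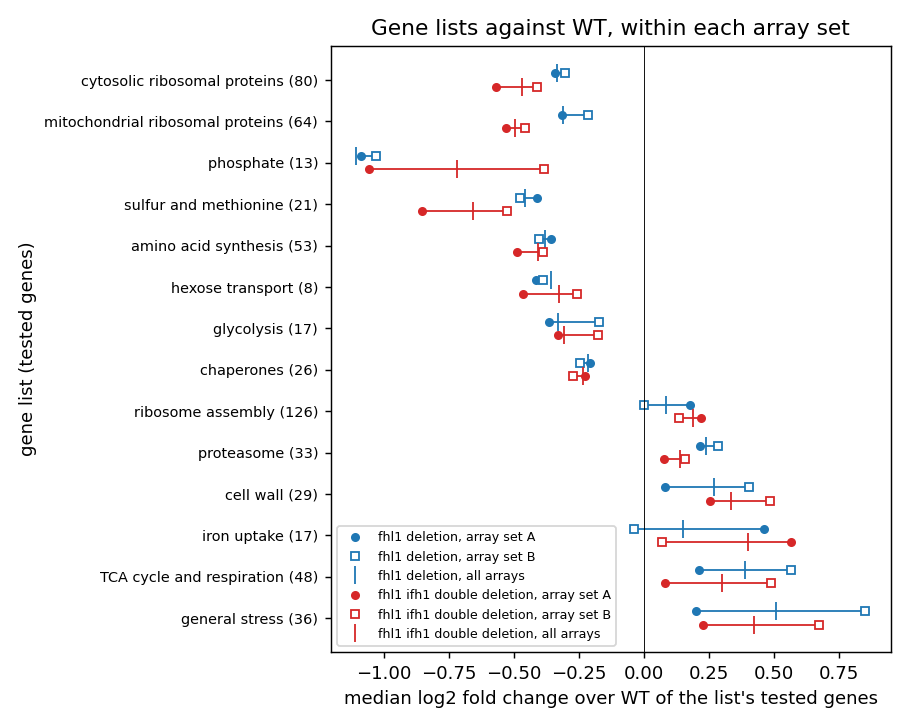
Median log2 fold change over WT of the tested genes of 14 gene lists (number in brackets), in blue for the FHL1 deletion and in red for the double deletion, with filled circles for array set A, open squares for array set B and a vertical bar for all arrays. The cytosolic ribosomal protein list lay at -0.33 and -0.47, the phosphate list at -1.11 and -0.72 and the general stress list at 0.51 and 0.42, with set B above set A for general stress.

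The double deletion differed from the FHL1 deletion at 1 of 4242 genes. That gene was IFH1, whose fall is only known to be at least 9.75-fold, and 213 genes had an unadjusted p under 0.05. The ribosomal protein list lay lower in the double deletion, with a median of -0.17 (set A -0.19, set B -0.09). In total 71 of its 80 genes were lower, although none passed alone, and none did when adjusted over the list alone. RPL33B had -0.56 (SE 0.16) and RPL25 -0.48 (SE 0.15), both with adjusted p = 0.95, and RPP2A had 0.34 (SE 0.11). The list gave adjusted p = 1.15e-06 in the set test and adjusted p = 0.551 with an estimated correlation, and without the double deletion array of the first experiment its median was -0.05 with adjusted p = 0.24. The 5 highest values by smallest p belonged to PTK1 at 1.01, the phospholipase gene PLB3 at 0.96, NCA3 at 0.95, PAC11 at 0.91 and the phosphate regulator gene PHO4 at 0.76, each with adjusted p = 0.473. PTK1 and NCA3 had adjusted p = 0.0473 with array set as a block, under which 5 genes passed. Over the 4 arrays with MATalpha markers 45 genes passed, but there 1 array stood against 1, with the spread taken from the WT arrays alone. Without the FHL1 deletion array of the first experiment 34 passed, and without the double deletion array of the first experiment 2.

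No member of any other list passed between the mutants, and 1 fall each in the sulfur and strain marker lists, both MET17 at -0.66 (SE 0.12, adjusted p = 0.473), passed when adjusted over the list alone. Lower medians passed the set test for mitochondrial ribosomal protein genes (-0.22, adjusted p = 7.6e-09), general stress (-0.20, adjusted p = 0.000945), sulfur (-0.23, adjusted p = 0.000465), respiration (-0.11, adjusted p = 0.0261) and the proteasome (-0.09, adjusted p = 0.0168). Higher medians passed for cell wall (0.13, adjusted p = 1.24e-07), iron (0.21, adjusted p = 0.00162), ribosome assembly (0.05, adjusted p = 0.00208), ergosterol (0.05, adjusted p = 0.0365) and phosphate genes (0.14, adjusted p = 0.0383). Every one of these had adjusted p of 0.551 or more with an estimated correlation, and respiration and phosphate each had adjusted p = 0.0529 with array set as a block. Within sets the phosphate median was -0.15 in A and 0.55 in B, and over the 4 arrays with MATalpha markers 3 of these 10 lists passed, those of cell wall, iron and sulfur genes, again with 1 array against 1. Several of these lists also depended on single arrays. Without the FHL1 deletion array of the first experiment general stress (-0.08, adjusted p = 0.525), respiration (adjusted p = 0.826), ribosome assembly (0.0064, adjusted p = 0.717), ergosterol (0.12, adjusted p = 0.0564), iron (0.13, adjusted p = 0.0554) and phosphate (adjusted p = 0.185) did not pass, and cell wall had 0.29 and sulfur -0.13. Without the second FHL1 deletion array cell wall (0.04, adjusted p = 0.058), ergosterol (adjusted p = 0.33) and the proteasome (-0.05, adjusted p = 0.269) did not pass, and respiration had -0.18 and ribosome assembly 0.09. Leaving out the double deletion array of the first experiment, general stress (adjusted p = 0.155), respiration (adjusted p = 0.489), ergosterol (adjusted p = 0.0863) and iron (0.09, adjusted p = 0.0908) did not pass, and cell wall had 0.27, phosphate 0.42 and the proteasome -0.16. Leaving out that of the second, phosphate (-0.155, adjusted p = 0.0979), ergosterol (0.02, adjusted p = 0.13) and the proteasome (-0.05, adjusted p = 0.595) did not pass, and cell wall had 0.03. Without the WT array of the second experiment phosphate had adjusted p = 0.055.

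Many genes were called in the same direction in both mutants against WT. The genes higher in both numbered 335 and those lower in both 260, and no gene was called in opposite directions. Independent lists would share 53.4 and 30.2. Lists of the same lengths shared 160.47 and 108.72 on average, and 183 and 131 at most, in 100 simulations without change in which only the shared WT arrays linked the comparisons. Part of the excess over independent lists may come from the shared controls. The called lists also shared 1 estimate of each gene's spread, whereas the simulations took the spread as known. The simulated overlaps leave out that link, so they cannot size its part in the observed overlaps. Across genes, which are not independent replicates, the fold changes correlated at 0.90, against a mean of 0.499 and a highest value of 0.621 in these simulations. Their covariance was 0.255 against 0.0221 simulated, a difference of 0.233. With separate WT arrays for each mutant, 1 array each, the correlation was 0.804 or 0.726 depending on which WT array served which mutant. The covariance was then 0.240 or 0.226, near that difference.

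**Figure D3:**
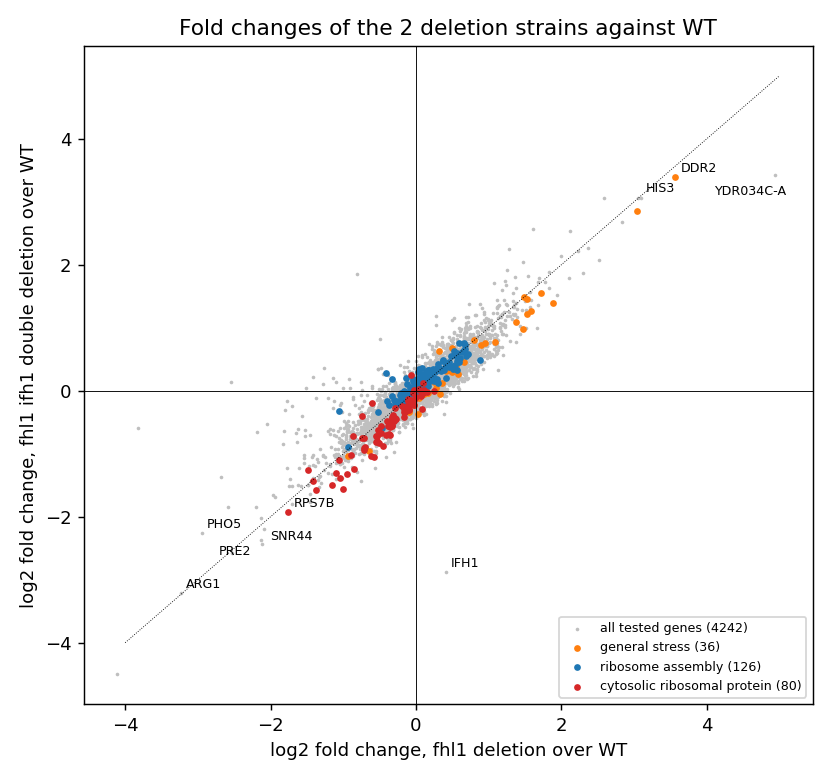
Log2 fold change of each of 4242 tested genes (points) in the FHL1 deletion over WT (horizontal axis) and the double deletion over WT (vertical axis), with 3 gene lists coloured and a dotted line of equal change. Points lay near the line (correlation 0.90), IFH1 lay at 0.41 and, at the floor in the double deletion, -2.88, and the 80 ribosomal protein genes were mostly below 0 in both.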

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

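The tests that weigh the ribosomal protein genes, PRE2 and the mating type markers were all chosen only after the result was seen.

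Probe sets that name no single gene lay outside the comparisons but held calls in both directions. Of 546 tested probe sets that name no gene, 46 were higher and 64 lower in the FHL1 deletion (median -0.35), and 41 higher and 26 lower in the double deletion (median -0.27). Of 240 tested probe sets that name several genes, 23 were higher and 41 lower in the FHL1 deletion (median -0.24), and 19 higher and 34 lower in the double deletion (median -0.30).

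The ribosomal protein genes were lower in both mutants, at medians of -0.33 and -0.47. A difference between arrays that depends on brightness was argued against among the named genes. The lowest of 10000 lists of such genes matched for brightness had medians of -0.113 and -0.0945. Probe sets that name no gene were not in those lists. Their medians were -0.35 in the FHL1 deletion and -0.27 in the double deletion, for which no brightness match was made. The mating type difference was argued against as the whole cause, since over the 4 arrays with MATalpha markers, 1 of each mutant, the medians were -0.34 and -0.55. A slower growth programme that lowers ribosome assembly genes as much was argued against too, since the lower quartile of those genes was at -0.0858 and 0.000368. A loss of FHL1 activity at these promoters may be the cause, as a hypothesis found on these arrays that no test here addressed; RNA integrity, which moved with the mutants, and a growth change that acts on ribosomal protein genes alone were not tested.

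PRE2, a proteasome subunit gene that lies next to FHL1, had -2.12 (adjusted p = 0.00253) and -2.44 (adjusted p = 0.00144) in the mutants. A change of the whole proteasome was argued against, since the median of the other 32 subunits was 0.25 in the FHL1 deletion (29 above 0) and 0.15 in the double deletion (25 above 0). An effect of the deletion next door could lower PRE2 equally in both mutants, and the double deletion differed from the FHL1 deletion by -0.32 (adjusted p = 0.982), which leaves it open, as both mutants lack FHL1. COG4, on the other side of FHL1, had 0.12 (adjusted p = 0.562) and 0.01 (adjusted p = 0.962). An effect of the FHL1 protein on the PRE2 promoter and an effect of the deletion on the neighbour cannot be told apart here.

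MATa markers were high on 2 of the 4 mutant arrays. WT RNA on those arrays was argued against, since their lower HIS3 value exceeded the higher WT value by 2.88, while the WT arrays differed by 0.146. This test adds no weight to the other explanations, because both WT arrays carried MATalpha markers and their RNA could not give the pattern. A mixture of cells of both mating types was argued against, since the higher MF(ALPHA)1 value on those arrays amounts to 1.87% of the mean of the MATalpha arrays and 2.86% of the lowest of them. MATa strains on those arrays are consistent with all 12 markers, 7 of MATa and 5 of MATalpha, each of which separated the 2 arrays from the other 4. The replicates of each mutant may therefore come from strains of different mating type, a hypothesis that the labels neither state nor exclude.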

How the results depend on the processing

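Array set as a block, the MATalpha arrays alone and the estimated correlation with array set as a block were chosen only after the data were seen; the cause was not tested for any change given here unless one is named. Genes called in the FHL1 deletion (903) became 505 with the experiment number as a replicate block and 1767 with array set as a block, and 243 to 859 with 1 array left out (319 and 243 without WT replicates 1 and 2, 472 without FHL1 deletion replicate 2). Those in the double deletion (774) became 315, 1577 and 461 with no filter, and 133 to 823 with 1 array left out (207 and 133 without WT replicates 1 and 2, 330 and 288 without double deletion replicates 1 and 2). Between the mutants the count of 1 became 5 with array set as a block, 45 over the MATalpha arrays and 1 to 34 with 1 array left out (34 without FHL1 deletion replicate 1, 2 without double deletion replicate 1). It was 0 of 2828 genes in limma with the lowest 50% left out (147 at an unadjusted p under 0.05), because IFH1 was then not tested. The correlation of 0.90 became 0.804 or 0.726 with separate WT arrays. Ribosomal protein medians kept their direction in all these alternatives, at -0.34 to -0.29, -0.55 to -0.37 and -0.23 to -0.0543 (FHL1 deletion, double deletion, between mutants) with 1 array left out. None of the alternatives was scaled to the bacterial control probe sets. Those differed from WT by -0.79 and -0.78 relative to the array median, more than the ribosomal protein medians did. Relative to these controls, the ribosomal protein medians of both mutants would thus lie above WT rather than below it. The size is uncertain, since the control median relative to the array median was -0.39 and -0.88 on the 2 double deletion arrays. With an estimated correlation the ribosomal protein values of -0.33, -0.47 and -0.17 had adjusted p = 0.551, and with array set as a block too 0.671, 0.671 and 0.697. Of the other lists 11, 12 and 10 passed, and 0 with an estimated correlation with or without that block; with 1 array left out 8 to 12, 9 to 13 and 5 to 11 passed, with 5 without FHL1 deletion replicate 1, and over the MATalpha arrays 3 of the 10 between the mutants. In the FHL1 deletion cell wall, chaperones and proteasome lost their call over those arrays, and cell wall with the mean of a gene's probe sets (adjusted p = 0.12). In both mutants against WT the hexose list lost it with quantile normalization, no filter, the lowest 50% left out and the mean of a gene's probe sets. The same held in the double deletion for glycolysis with quantile normalization (adjusted p = 0.06) and iron with the lowest 50% left out (adjusted p = 0.0672), and between the mutants for respiration with quantile normalization (adjusted p = 0.062) and phosphate with no filter (adjusted p = 0.0866) or only the arrays compared (adjusted p = 0.0537). Values that turned were RDN37-1 in the double deletion, 2.02 (adjusted p = 0.418) with the floor at the 25th percentile, where another of its probe sets became the brightest; hexose transport in the FHL1 deletion, 0.0274 with the mean of a gene's probe sets and -0.44 to 0.0374 with 1 array left out; and phosphate between the mutants, -0.15 over the MATalpha arrays and -0.16 to 0.42 with 1 array left out. With 1 array left out, and over the MATalpha arrays, which hold 1 array of each mutant, a lone array was assumed to vary like those of the other groups. With 1 array left out 1084 results for named genes were the same, 233 weaker and 2 stronger, and for lists 202 were the same, 30 weaker and 2 turned. Signal over background limits FHL1, which lay under the floor, and 1414 genes too dim to test.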

Other observations

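The snoRNA test was chosen only after the result was seen, and so were the genes named in this part.

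Some single genes outside the lists that passed are given without a count of related genes. The glycine cleavage gene GCV3 (1.38 in the FHL1 deletion, 1.40 in the double deletion) passed the threshold in both mutants, though not in the double deletion without the WT array of the second experiment (1.08, adjusted p = 0.0512). ARO10, a phenylpyruvate decarboxylase gene (1.57 and 1.57), and the proline permease gene PUT4 (1.51 and 1.43) passed in both as well. HMO1, a promoter partner of FHL1, had -0.33 (adjusted p = 0.113) and -0.30 (adjusted p = 0.159). Its scaled values were 11.25 and 11.38 in WT and lower on every mutant array, at 10.93 to 11.08. RAP1, which binds the same promoters, had -0.37 and -0.06, and SFP1, a growth regulator gene, had 0.18 and 0.37, none past the threshold. Other genes examined with these did pass in the FHL1 deletion, besides UTP22. ESA1 had 0.79 (adjusted p = 0.0143), YAK1 0.76 (adjusted p = 0.0473) and CKA1 -0.71 (adjusted p = 0.0327). In the double deletion they had 0.54 (adjusted p = 0.0469), 0.83 (adjusted p = 0.0418) and -0.59 (adjusted p = 0.0613). These calls did not hold without the WT array of the second experiment. There YAK1 had 0.45 in the FHL1 deletion and 0.51 in the double deletion. The CKA1 call in the FHL1 deletion ended without any single array of that comparison.

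Some small RNA genes fell in both mutants besides SNR44 and SNR39. RPR1, the RNA of RNase P, had -1.73 and -1.40, and the small nucleolar RNA SNR13 had -1.42 and -1.39, all past the threshold, although RPR1 was too dim to be tested when the first or the second WT array was left out. SNR44 lies in an intron of RPS22B and SNR39 in one of RPL7A. A candidate explanation is that snoRNAs inside other genes follow their hosts. Among snoRNAs with a mean above 7.31 in at least 1 group, the only others inside genes were SNR38 in TEF4 and SNR54 in IMD4. Both were too dim for the gene tests. They averaged -1.72 and -1.36, against medians of -0.49 and -0.56 for 24 snoRNAs outside genes (exact one-sided permutation test over 325 combinations, p = 0.00923 and p = 0.0123). The test cannot decide, since SNR38 and SNR54 passed that cut in WT alone (8.36 and 7.93), which favours falls. It also treated all snoRNAs as independent. The host TEF4 fell (-0.60, adjusted p = 0.0165, and -0.57, adjusted p = 0.0233). TEF4 had -0.61 and -0.58 without the WT array of the first experiment, which left 1 WT array. Its call ended there, and also when any other array of the comparison was left out. RPL7A had -0.29 (adjusted p = 0.0535) in the FHL1 deletion and -0.43 (adjusted p = 0.0216) in the double deletion. The latter call ended when any array of that comparison was left out. IMD4 had -0.27 (adjusted p = 0.171) and -0.29 (adjusted p = 0.158). Of the 24 snoRNAs outside genes, 14 and 16 were below 0 too, so the host effect stays open.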
